A study of Homo sapiens with 6 samples.

How the data were processed

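RNA immunoprecipitation (RIP) followed by small RNA sequencing was carried out in Kasumi-1 cells that stably expressed V5-tagged AES. The series has 6 samples: 1 RIP with an antibody against the V5 tag (AES), 3 RIPs with an antibody against DDX21, and 2 RIPs with control IgG. Values were at hand for 4 of them, the AES sample and the 3 DDX21 replicates. The IgG samples were not analysed here, so no enrichment over control was computed. Libraries were made with a small RNA kit and selected by insert size, per the labels' protocols. Adapter trimming and alignment software were cutadapt 1.6 and Bowtie2 2.2.4, and the genome build was hg19, per the submitters' processing notes. The peak caller, the counting rule, the treatment of reads that align to several places and the part played by the IgG libraries are not given in the sources used here.

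Each file lists genomic regions with a strand and 1 value per region. The unit was not stated in the file headers and was read from the values: the authors' deposited values were RPM, reads scaled to 1000000 reads of the library, not divided by region length. In each file 100% of the values lay within 0.001 RPM of a whole multiple of 1 step, and 1000000 divided by that step gave a whole number. The library totals found in this way were 968304 reads for AES and 557197, 237351 and 1866783 reads for DDX21 replicates 1, 2 and 3. The smallest listed value was 20 reads in the AES file and 6 reads in the file of DDX21 replicate 3. The totals of these libraries therefore rest on the spacing of the values alone, and no test on counts was run. Intervals on shares of reads are exact Clopper-Pearson 95% intervals from these totals and cover counting error only, since reads copied by PCR are not independent molecules. A count of 3 reads, used as the floor, corresponds to 3.10 RPM in AES and to 5.38, 12.6 and 1.61 RPM in DDX21 replicates 1, 2 and 3.

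Regions lie on a grid of 50 bp. The smallest start in the files is 0, so starts were read as counted from 0 and 1 was added for printing. Coordinates are in hg19 as deposited. The annotation at hand (GENCODE v29) is on GRCh38 and was not transferred to the hg19 chromosomes. The files hold no gene names, so the regions on chromosomes are given by position, and snoRNA names, snoRNA classes, exons and introns are not stated. The planned counts of C/D box and H/ACA box snoRNAs and of gene lists fixed in advance, the planned Fisher test of the overlap against annotated snoRNAs, and the parts of the naming rule that need names were therefore not run. The exception is the unplaced scaffold chrUn_gl000220, which is the same versioned sequence in both builds, so that its annotated 5.8S rRNA genes could be read without any change of coordinates.

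The main comparisons, the rule for named regions and most alternatives were fixed before the data were examined. Regions were named when they were among the 10 highest by mean DDX21 RPM, the 10 highest by AES RPM, or the 10 highest or 10 lowest by AES over mean DDX21 among regions in which AES lay on the same side of each DDX21 replicate. Regions listed for 1 protein and regions past the range rule are also named; these were chosen after their values were seen. The DDX21 list was counted as the regions with reads in all 3 replicates. Overlap required 1 bp on the same strand. DDX21 replicates were compared by Spearman's rank correlation across regions, which are not independent replicates. No Jaccard index was needed, because the 3 DDX21 files list the same regions.

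AES and DDX21 values were compared on the log2(RPM + 1) scale over the 346 regions listed for both. AES was called higher or lower when it lay beyond the highest or lowest DDX21 replicate by more than the range of the 3 replicates. An exact permutation test of 1 sample against 3 cannot go below p = 0.25 and was not run per region. limma 3.58.1 in R 4.3.3, with a trend in the variance and Benjamini-Hochberg adjustment, was added as an alternative after seeing the data. Log2 ratios are of AES to the mean of the 3 DDX21 values, with 1 RPM added to both, which understates differences at low values. Other alternatives were pseudocounts of 0.1 and 5, filters on low values, scaling to the median of the shared regions, and leaving out each DDX21 replicate. The labels do not say whether the DDX21 replicates came from separate cultures, so their spread may be technical.

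The range rule and limma were tested on simulated data for the comparison of AES with DDX21, with 346 regions of which 60 were changed. At a 4-fold change the range rule recovered 80% of the changed regions and also called 13.3% of the unchanged ones, while limma recovered 40% and called 0% of the unchanged ones. At a 16-fold change both recovered 100%, with 14.3% and 1.05% of unchanged regions called. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.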

Results

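The series asked which small nucleolar RNAs (snoRNAs), the guides of rRNA modification and processing, bind AES and DDX21. AES (amino enhancer of split) is a short member of the Groucho/TLE family of transcriptional co-regulators, and DDX21 is a nucleolar DEAD-box RNA helicase involved in rRNA production. Kasumi-1 is an acute myeloid leukaemia cell line that carries the AML1-ETO fusion gene. RNA recovered by immunoprecipitation of each protein was sequenced as small RNA, with 1 AES library and 3 DDX21 replicates analysed here. The AES list held 387 regions that took up 78.4% of the reads of a library of 968304. The DDX21 list held 1043 regions, which took up 86.5%, 91.7% and 85.9% of libraries of 557197, 237351 and 1866783 reads. Without values for control IgG, the level of a region is its share of the library and not an enrichment. AES values come from 1 library and have no replicate error.

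The RNA recovered with DDX21 was led by rRNA. The scaffold chrUn_gl000220, which carries 2 copies of the rRNA gene unit, took up 31.6% ± 5.51 of the reads (SD, n = 3) in 19 regions. The highest regions in the list covered the 5.8S rRNA genes RNA5-8SN2 (ENSG00000274917.1, positions 112025 to 112177, plus strand) and RNA5-8SN4 (ENSG00000273730.1, 155997 to 156149, plus strand). They held 66755 ± 18421 RPM (region 111951 to 112200) and 66667 ± 18141 RPM (region 155901 to 156150; SD, n = 3). Next came the wide regions upstream of these genes, on the side of the unit where the 18S rRNA lies, with 40341 ± 3552 RPM at 153301 to 154850 and 39850 ± 3547 RPM at 109151 to 110800. A region downstream, on the 28S side, at 116901 to 118400, held 14513 ± 6869 RPM. Both gene units are near-identical in sequence, so reads of 1 unit cannot be assigned to it with certainty.

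**Figure D1:**
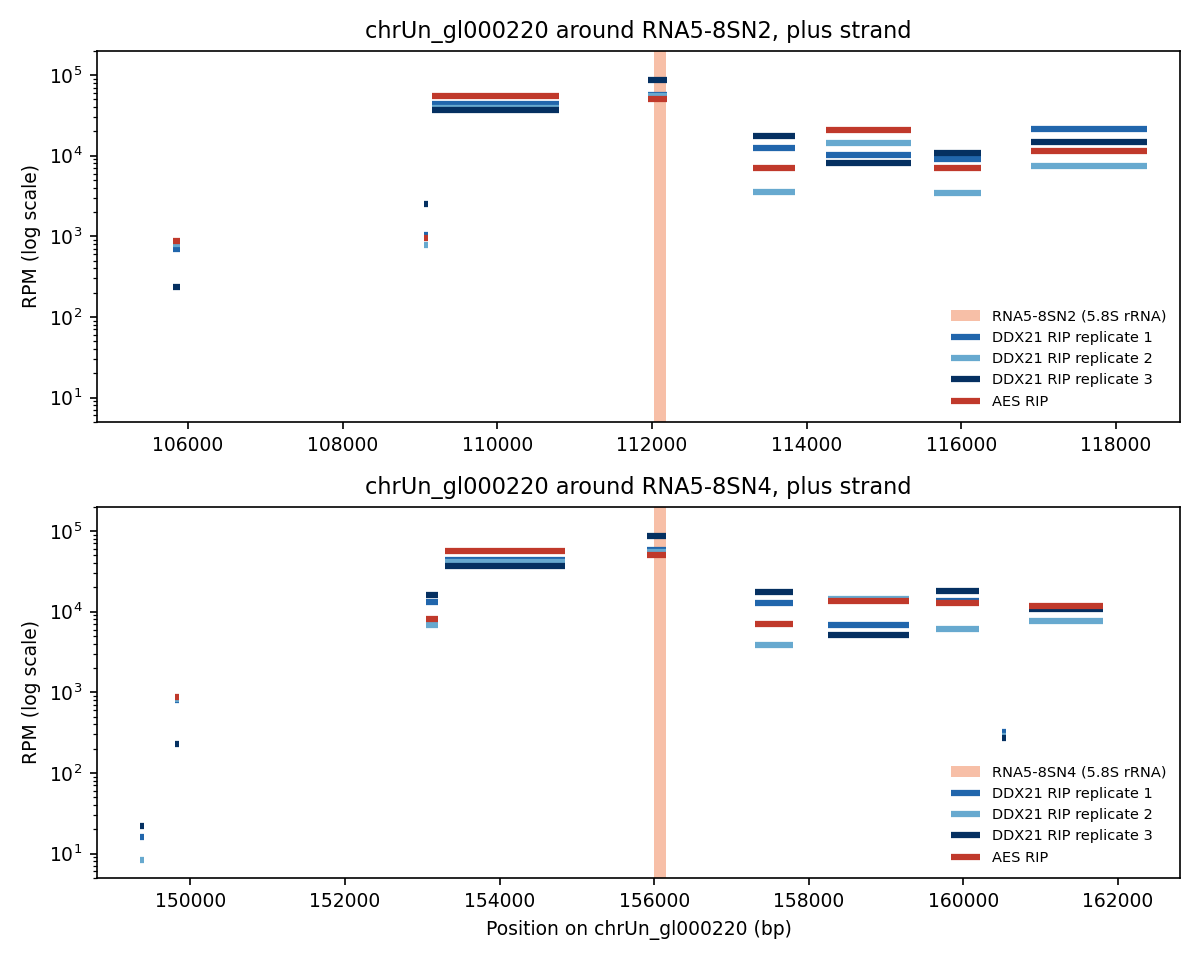
RPM (log scale) of listed regions against their position in bp on the scaffold chrUn_gl000220, near RNA5-8SN2 (upper panel) and RNA5-8SN4 (lower panel); each bar spans 1 region in 1 library and the shaded band is the annotated 5.8S rRNA gene. In both units the AES bar lies below the DDX21 bars over the 5.8S gene and above them in the wide upstream region.

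Outside the rRNA scaffold, the assembled chromosomes held 951 of the DDX21 regions and 51.5% ± 9.08 of the reads, and the mitochondrial genome held 41 regions and 3.08% ± 0.534 (SD, n = 3). The highest chromosomal region was chr11:62621351-62621450 on the minus strand, with 30478 ± 25257 RPM. It was followed by chr19:12814401-12814450 (minus) with 22584 ± 26758 RPM, chr12:20704351-20704500 (plus) with 21636 ± 1684 RPM and chr16:89627801-89627900 (plus) with 20242 ± 9869 RPM. The last of the 10 highest regions, chr11:109473901-109473950 (plus), held 14442 ± 14145 RPM and was not in the AES list. These regions differed widely in how well the replicates matched. The chromosome 12 region spanned a 1.16-fold range over the 3 replicates, whereas the chromosome 19 region spanned 22.4-fold, from 2362 RPM in replicate 3 to 52926 RPM in replicate 2.

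Of the 1043 DDX21 regions, 995 had reads in all 3 replicates. The other 48 were listed at 0 in at least 1 replicate, which for replicate 2 allows a level of up to 12.6 RPM. Across the 1043 regions, Spearman's rho was 0.865 between replicates 1 and 2, 0.883 between replicates 1 and 3, and 0.748 between replicates 2 and 3. The median region spanned a 2.33-fold range over the replicates, and 131 regions spanned more than 3 units of log2. Leaving out replicate 2 or replicate 3 leaves 1 pair, so the lowest correlation is then the value of 0.883 or 0.865 just given.

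The AES RIP recovered mostly the same leading regions as the DDX21 RIP, in another order. Its highest region was chr11:62621351-62621450 (minus), with 61657 RPM. The wide regions upstream of the 5.8S genes came next, with 56050 RPM at 153301 to 154850 and 55170 RPM at 109151 to 110800 of chrUn_gl000220. The 5.8S regions themselves held 50223 RPM (RNA5-8SN4) and 49977 RPM (RNA5-8SN2). Then followed chr19:12814401-12814450 with 44663 RPM, chr12:20704351-20704500 with 28539 RPM, the downstream rRNA region at 114251 to 115350 with 20976 RPM, chr16:89627801-89627900 with 15384 RPM and chr11:62620801-62620850 (minus) with 15140 RPM. Of these 10 regions, 8 were also among the 10 highest for DDX21. The rRNA scaffold took up 31.4% of the AES library (exact 95% binomial interval 31.3 to 31.5%), close to the DDX21 mean of 31.6% ± 5.51 (SD, n = 3). The AES list included 11 mitochondrial regions, with 1.79% of the reads (interval 1.76 to 1.81%), against 1.94% ± 0.237 over the same regions in DDX21.

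Most of the AES list was shared with DDX21, but without control values this does not show that the proteins bind overlapping sets of RNA. Of the 387 AES regions, 345 overlapped a DDX21 region with reads in all 3 replicates, a share of 89.1% (exact 95% interval 85.6 to 92.1%). With any DDX21 region allowed, 346 overlapped, and each of these had the same start and end in both lists. This included the 140 overlapping regions wider than 50 bp. The lists therefore cannot be taken as called independently of each other, and the share does not measure agreement between independent lists. In the other direction, 33.2% of the DDX21 regions were in the AES list (interval 30.3 to 36.1%). That share depended on level: with the DDX21 regions ranked by mean RPM and divided into 4 parts, it was 9.20% in the lowest part, 13.03% and 41.5% in the next ones, and 69.0% in the highest. The calling rule behind the lists is not given in the sources used here, and an unlisted region is not a measured 0. The intervals on shares of regions take regions as independent, which neighbouring or near-identical regions are not. They do not cover differences between AES libraries.

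Several abundant DDX21 regions had no counterpart in the AES list. After chr11:109473901-109473950, the highest were chr1:17004801-17004850 (minus) with 8183 ± 5184 RPM, chr6:27248051-27248100 (minus) with 6489 ± 10260 RPM, chr17:33478151-33478250 (minus) with 5685 ± 3269 RPM and chr2:11691801-11691900 (plus) with 5234 ± 4106 RPM (SD, n = 3). The chromosome 6 value came mostly from replicate 2, at 18336 RPM, against 479 RPM in replicate 1 and 651 RPM in replicate 3. The mitochondrial region at 14701 to 14750 (plus) was steadier, with 3859 ± 1184 RPM. Of the 41 regions listed for AES alone, the highest was chr4:120158601-120158650 (plus) with 669 RPM, and 10 lay together between 201299551 and 201302000 on chromosome 1. On the opposite strand, 3 AES regions overlapped a DDX21 region, 2 of them with the same limits. The DDX21 files held only 2 opposite-strand pairs, so a region listed for AES alone can lie over a DDX21 region of the other strand.

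Over the 346 regions listed for both proteins, AES and DDX21 values followed each other closely. Spearman's rho of AES was 0.952 with DDX21 replicate 1, 0.942 with replicate 2 and 0.910 with replicate 3, while the DDX21 replicates gave 0.890 to 0.957 among themselves. AES passed the range rule in 47 regions, 32 higher and 15 lower. After scaling each library to its median over the shared regions, 20 were higher and 15 lower, with 12 higher and 9 lower under both scalings. That scaling moved the median log2 ratio of AES to DDX21 from 0.25 to -0.06, so ratios near 0.25 have no fixed direction. AES passed the range rule in more regions than DDX21 replicate 1 did, in as many as replicate 2 and in fewer than replicate 3. Each library set against the other 3 gave 47 regions for AES (13.6% of 346), 7 for DDX21 replicate 1, 47 for replicate 2 and 72 for replicate 3, and simulated unchanged regions passed in 13.3% of cases. Leaving out DDX21 replicate 1, 2 or 3 gave 81, 109 or 68 regions higher in AES and 24, 34 or 45 lower, and limma called 0 regions at an adjusted p of 0.05 (smallest 0.767; 10 at an unadjusted p under 0.05).

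None of the regions listed next passed limma. The range rule favours regions in which the 3 DDX21 values happen to lie close together. The SDs printed for regions past the rule, higher or lower, are therefore biased to be small and do not measure how sure a difference is. The 12 regions that were higher in AES by the range rule under both scalings included chrUn_gl000229:18751-18900 (plus), with 3855 RPM against 1648 ± 71.0 RPM in DDX21, a 2.34-fold difference. Another was chr2:133012851-133012950 (minus), with 1949 RPM against 840.1 ± 155 RPM (SD, n = 3). On chromosome 18, the neighbouring regions 47018001 to 47018050 and 47017851 to 47017900 (minus) were 1.72-fold and 2.28-fold higher in AES. The region of the largest ratio in this group was chr1:145277401-145277450 (plus), with 208 RPM against 81.8 ± 11.1 RPM. Further members were chr1:161391851-161391950 (minus, 1.71-fold), chr20:47897201-47897250 (plus, 1.62-fold) and chr13:50623201-50623250 (minus, 2.13-fold). The values of the chr1:161391851-161391950 and chr20 regions differed by under 0.5 log2 units in each library, so these regions may not be separate loci.

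The 9 regions that were lower in AES by the range rule under both scalings, none of which passed limma either, included chr7:22896201-22896300 (plus), with 279 RPM against 567 ± 66.98 RPM in DDX21, and chr1:566451-566500 (plus), with 233 RPM against 409 ± 55.9 RPM (SD, n = 3). The most abundant was chr1:173835101-173835150 (minus), with 8795 RPM against 13346 ± 1417 RPM, a 1.52-fold difference. Of the 9, 4 lay on alternative haplotypes of chromosome 6, with 291 to 299 RPM in AES and DDX21 means of 462 to 480 RPM. Their values were nearly equal in each library and haplotypes are versions of the same chromosome part, so these regions cannot be counted as separate loci. The mitochondrial region 14101 to 14350 (minus) was 1.49-fold lower, with 330 RPM against 493 ± 8.84 RPM. This SD is small by selection, since 1 read of DDX21 replicate 2 alone corresponded to 4.21 RPM. The values of chr1:566451-566500 were near those of the mitochondrial region 5901 to 5950 (plus), with 228 RPM in AES and 403 ± 66.5 RPM in DDX21. Reads of 1 sequence divided between both places cannot be told apart from separate RNAs of similar level.

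**Figure D2:**
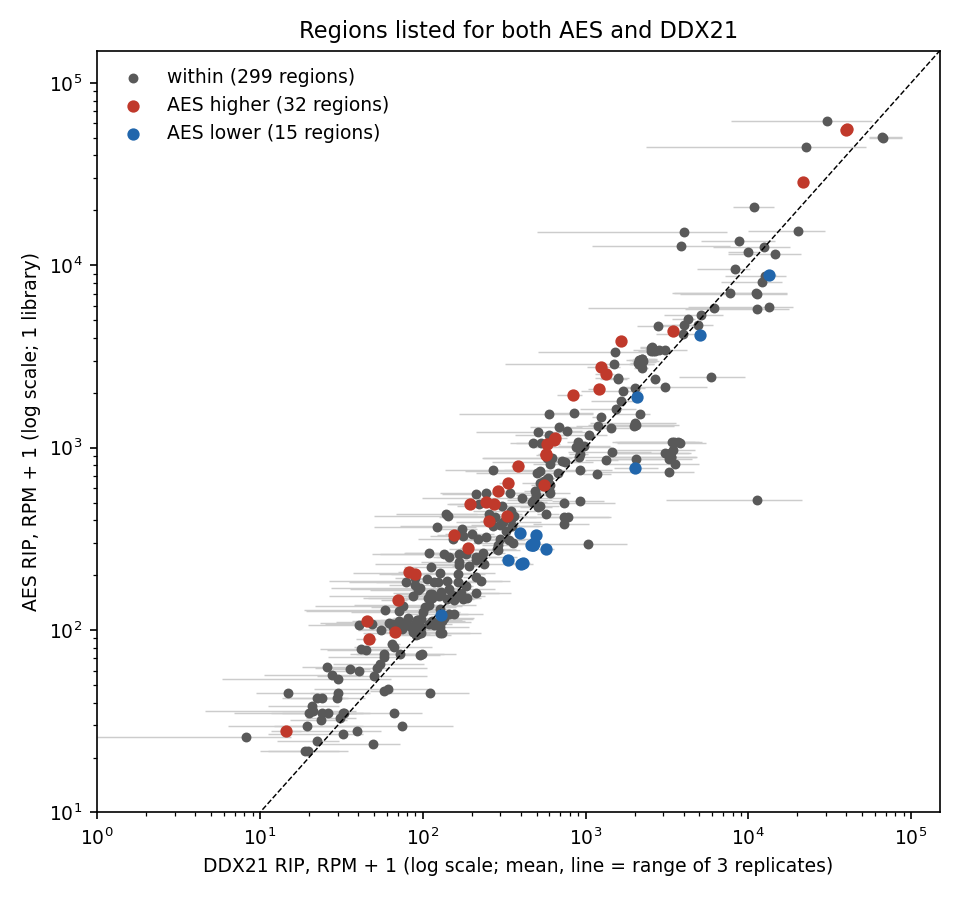
AES RPM plus 1 (1 library) against mean DDX21 RPM plus 1, both on log scales, for the 346 regions listed for both; grey lines span the 3 DDX21 replicates, red and blue points are the 32 and 15 regions past the range rule, and the dashed line marks equal values. The points follow the dashed line over the whole range, and wide replicate ranges occur at low and at high levels.

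Within the rRNA gene unit, no part differed between AES and DDX21 by the range rule under both scalings. Over the 5.8S genes AES held 10.02% of its reads, below each DDX21 replicate (13.3% ± 3.66, SD, n = 3). In the regions upstream it held 12.2%, above each replicate (9.49% ± 0.723). The ratio of 5.8S to upstream reads was 0.822 in AES and 1.11, 1.23 and 1.90 in DDX21 replicates 1, 2 and 3. AES thus lay 0.44 log2 units below the lowest replicate, less than the replicates' range of 0.77, and did not pass the range rule. Downstream, AES held 9.18% against 8.69% ± 2.28. The upstream difference passed the range rule in RPM but not after scaling to the median, where its log2 ratio was 0.02, and the 5.8S difference passed it in neither case.

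The largest ratios of AES to DDX21 stood mostly at regions where the DDX21 replicates lay far apart, and none of the 20 regions named for them passed the range rule in RPM. On the high side, chr11:62620801-62620850 (minus) held 15140 RPM in AES against 4026 ± 3463 RPM, and chr1:173833251-173833350 (minus) held 12687 RPM against 3834 ± 3482 RPM (SD, n = 3). The others of the 10 ranged from a log2 ratio of 1.39 at chr21:45744001-45744050 to 1.65 at chr13:25670651-25670700, where AES held 24.8 RPM. They included chr19:3982501-3982550, chr2:73799701-73799750, chr1:45242151-45242200, chr1:86057951-86058000, chr19:12817251-12817300 and chr11:45848151-45848250. In 7 of the 10, replicate 2 was the highest DDX21 library and replicate 3 the lowest, an order found in 130 of the 346 shared regions (37.6%). Without replicate 2 the log2 ratio rose from 1.91 to 2.70 at chr11:62620801-62620850 and from 1.73 to 2.76 at chr1:173833251-173833350. It rose from 1.58 to 2.23 at chr1:45242151-45242200 and from 1.57 to 2.56 at chr1:86057951-86058000. Without replicate 3 these ratios fell to 1.39, 1.29, 1.21 and 1.17, in the same order. At chr13:25670651-25670700 the ratio went from 1.65 to 2.49 without replicate 3 and to 1.13 without replicate 2. On the low side, chr7:98479301-98479500 (plus) held 517 RPM in AES against 11287 ± 9357 RPM, a 21.8-fold difference, with 3119 RPM in the lowest DDX21 replicate. Its log2 ratio of -4.44 became -3.58 without DDX21 replicate 2.

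The other 9 low regions had log2 ratios between -2.14 and -1.79. Of these, 8 lay on chromosomes 1, 3, 5, 6, 16 and 17 and held 737 to 1064 RPM in AES. They were chr5:85668651-85668700, chr16:70822551-70822600, chr16:70812951-70813000, chr16:70812101-70812200, chr3:15549451-15549500, chr17:8029051-8029100, chr6:27870701-27870750 and chr1:161493651-161493700. The last was the mitochondrial region 15801 to 16000 (minus), with 296 RPM against 1029 ± 724 RPM (log2 ratio -1.79, and -1.11 without replicate 2), whose values were identical to those of a plus-strand region that overlaps it in the DDX21 files. After scaling to the median, chr7:98479301-98479500 and chr1:161493651-161493700 passed the range rule.

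**Figure D3:**
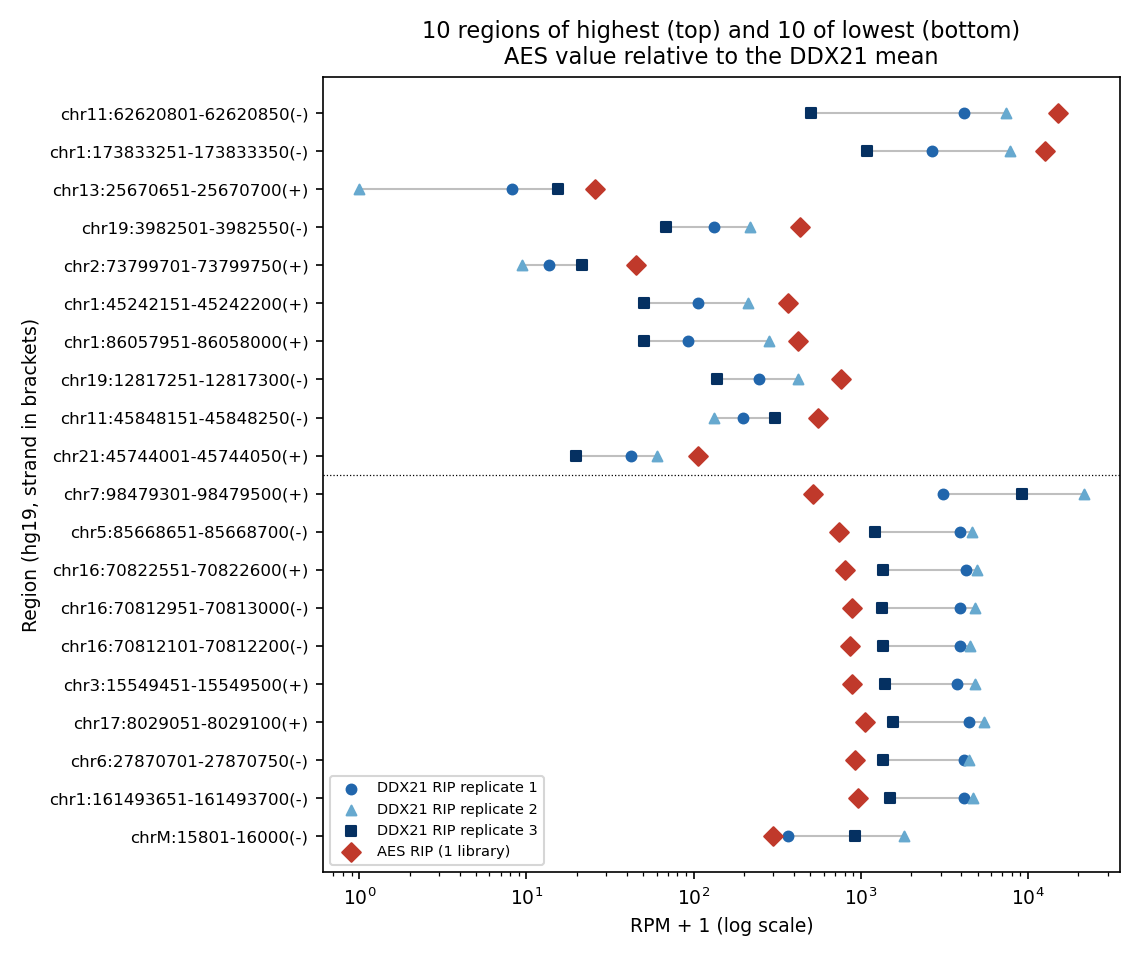
RPM plus 1 (log scale) in each library for the 10 regions of highest and the 10 of lowest AES value relative to the DDX21 mean; diamonds are the AES library, other symbols the 3 DDX21 replicates, and grey lines their range. AES lies outside the range of the replicates in each region because the regions were chosen for this, and 8 of the 10 low regions hold close to the same values.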

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

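The limma fit, the reduction to 1 region per group of near-equal regions and the tests of the rRNA scaffold share were chosen after the data were examined; the other alternatives were planned. Keeping the upper part of each list by median RPM left 522 DDX21 regions and 194 AES regions by construction and raised the overlap of the AES list to 99.5%. The lowest rank correlation between DDX21 replicates ran from 0.748 to 0.883 when each replicate was left out, which is the value of the 1 pair that remains. AES was higher in 20 regions after scaling to the median, in 68 to 109 without 1 DDX21 replicate, and in 0 with limma. AES was lower in 24 to 45 regions without 1 DDX21 replicate and in 0 with limma. The range rule is met more easily with 2 DDX21 libraries, whose range is narrower. Each of the other 29 recomputed values of main results stayed within 1.5 times its count or within the replicate spread or interval. The same held for 140 recomputed log2 ratios of named regions. None of these changed sign, but the regions were chosen with AES on the same side of each DDX21 replicate. Only scaling to the median could therefore have changed a sign. Several of the 29 values were likewise fixed, or nearly so, by construction. Leaving out the lowest of 4 parts by level set the sizes of the lists, 779 DDX21 and 290 AES regions. A stricter overlap could not change the share of 89.1%, because overlapping regions had the same limits. Leaving out a DDX21 replicate could hardly change it, because the DDX21 files list the same regions. These values do not show that the results are robust. The ratio of AES to DDX21 for the rRNA scaffold share ran from 0.915 to 1.09 without 1 DDX21 replicate. Counts of snoRNA classes and of gene lists were not run, because the files hold no names. No paired analysis was possible because AES has 1 sample and the IgG replicates were not analysed here. DDX21 replicate 2 was the shallowest library and listed 39 regions at 0, and whether depth explains them was not tested.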

Other observations

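Regions within 10000 bp of each other on 1 strand were joined into clusters, and 15 clusters held at least 7 regions; the clusters and the tests in this part were chosen after the data were examined, and those on near-equal low regions and on opposite strands after their results were seen. On the minus strand of chromosome 1, between 228746001 and 228781900, 17 regions followed each other at a spacing of 2200 to 2250 bp. The 5S rRNA genes, as background, form a tandem array on the long arm of chromosome 1, but no annotation of this build was used here. AES listed 16 of the 17 DDX21 regions in this cluster, against 9.997 for regions of the same DDX21 level (permutation p = 0.0021, adjusted p = 0.0252 over 14 clusters). Summed over the 16, AES held 9491 RPM and DDX21 8344 ± 552 RPM (SD, n = 3). On the plus strand of the mitochondrial genome, AES listed 5 of 26 DDX21 regions, against 11.8 at the same level (permutation p = 0.0036, adjusted p = 0.0252). Fisher's exact test, which takes no account of level, gave adjusted p = 2.82e-06 for the chromosome 1 cluster and 0.288 for the mitochondrial one, so the latter departs only from regions of its own level. It also passed for the chromosome 1 cluster between 173833251 and 173836850 (adjusted p = 0.0273) and both rRNA scaffold clusters (adjusted p = 0.00621 and 0.0147). These p-values count regions as independent, which neighbouring or near-identical regions are not.

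The other 12 clusters with DDX21 regions did not pass the level-matched test (adjusted permutation p of 0.888 or above). On the minus strand of chromosome 1, between 173833251 and 173836850, AES listed 7 of 9 regions and held 24460 RPM, against 18665 ± 4178 RPM in DDX21 (SD, n = 3). Between 62620801 and 62623100 on chromosome 11, 5 of 7 were listed, and AES held 79510 RPM against 36270 ± 29420 RPM. In the imprinted Prader-Willi part of chromosome 15, between 25296601 and 25351700 (plus), 6 of 19 regions were listed, with 643 RPM in AES and 789 ± 436 RPM in DDX21. Of the clusters summed over shared regions, the one on chrUn_gl000229 between 18201 and 19850 (plus) was higher in AES by the range rule. It held 4119 RPM against 1883 ± 171 RPM. The one on chromosome 1 between 564851 and 568950 (plus) was lower, with 1009 RPM against 2422 ± 724 RPM. After scaling to the median both lay within the range rule. The shared regions of this chromosome 1 cluster lie at 1 offset from listed mitochondrial regions, so the cluster cannot be counted as separate from the mitochondrial genome. Between 25656651 and 25685250 on chromosome 3 (minus), AES listed 0 of 7 regions, which summed to 272 ± 21.3 RPM in DDX21. The cluster of 10 regions between 201299551 and 201302000 on chromosome 1 (plus) was listed for AES alone, with 27.9 to 230 RPM per region and 999 RPM in all. It rests on 1 library. Random draws of regions were run but say nothing about chance here, since the cluster was noticed for this property and its neighbouring regions are not independent.

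DDX21 replicates 2 and 3 had the lowest rank correlation, 0.748. Noise of read counting alone in the shallow replicate 2 is argued against: libraries drawn from the mean DDX21 profile at both depths gave a median correlation of 0.974, above the observed value in 200 of 200 draws. The draws take reads as independent, so noise from a small number of distinct molecules copied by PCR was not tested and stays open. Keeping 1 region per group of near-equal values gave 0.693 over 967 regions, so the correlation did not rise. This cannot decide whether copies counted as separate regions play a part. The groups were made from the values, without sequence, and only among regions with at least 2000 reads, so copies with fewer reads stayed separate. A difference between these preparations may remain, but the labels name no batch or day, so no biological explanation was tested.

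Of the 10 regions of lowest AES value relative to DDX21, 8 held almost the same values as each other. The exceptions were chr7:98479301-98479500 and the mitochondrial region 15801 to 16000. Of the 10 lowest, 6 belonged to 1 group of 7 regions on 5 chromosomes whose values differed by under 0.5 log2 units in each library. The groups were made from the values alone, without sequence, so this count restates the pattern, and reads of near-identical copies divided among the listed positions cannot be told apart from separate RNAs of similar level. The summed group held 6045 RPM in AES and 23114 ± 12174 RPM in DDX21 (SD, n = 3). It lay below the lowest DDX21 replicate by 0.35 of the DDX21 range, so a lower level of this group in AES and the spread between replicates cannot be told apart with 1 AES library.

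Regions on opposite strands of the same place held identical values. In the DDX21 files 2 pairs of mitochondrial regions overlapped on opposite strands, at 5801 to 5850 and at 15901 to 16000, and 6 of 6 pairs of values over the 3 libraries were identical. The pair at 5801 to 5850 has the same limits on both strands, which gave 3 of 3 identical values, at up to 351 reads. In the other pair the minus-strand region is wider, from 15801 to 16000, so its identical values, at up to 1712 reads, would also need all of its reads to be counted for the shared part. The pair with equal limits is consistent with reads counted without regard to strand, in which case the strand of a region would come from its calling and not from its value. No biological explanation was tested.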
